A study of Mus musculus with 16 samples.

How the data were processed

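The samples were 16 livers of 16-week-old mice in 4 groups of 4, grouped as the labels name them: Alb-Cre control, E2f7/E2f8 knockout, Pten knockout and Pten/E2f7/E2f8 knockout. The design text instead names the E2f7/E2f8 knockout samples liver tumors and the controls wild-type, and the labels were followed. Per the labels, frozen liver was pulverised, RNA was extracted with a Qiagen RNeasy kit and libraries were made with the Illumina TruSeq PolyA kit. The deposited values were raw counts per Ensembl gene, made by the authors before deposition. BWA and the builds GRCm38 and mm10 are named in their processing notes, while the counting tool, its annotation and its use of strand are not stated. The table held 47069 gene IDs, of which 46488 were matched to a symbol and 46574 to coordinates.

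Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with the group, which left 14844. Libraries were scaled with TMM factors, and 1 quasi-likelihood fit (robust) with a mean per group was made over all 16 libraries, with no covariate. The comparisons were E2f78DKO, PtenKO and TKO against control, TKO against PtenKO and against E2f78DKO, and the interaction, (TKO minus PtenKO) minus (E2f78DKO minus control). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values used TMM-scaled library sizes. The p-values rest on the spread between libraries within groups, here 4 livers each, estimated over all groups of the fit. Libraries of groups that are not compared therefore also bear on them.

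Depth ran from 18557270 to 61966456 counts, and the common biological coefficient of variation was 0.249. The lowest chi-square per degree of freedom between replicates was 17.3 (E2f78DKO 2 and 4), so spread between livers exceeded counting error. Calling was tested on simulated data in which 200 genes were changed. Of 67 genes changed 2-fold, 49.3% were recovered for E2f78DKO against control, 49.3% for PtenKO against control, 68.7% for TKO against control, 49.3% for TKO against PtenKO, 55.2% for TKO against E2f78DKO and 20.9% for the interaction. With the library set in the model these were 43.3%, 20.9%, 67.2%, 22.4%, 53.7% and 7.46%. For 66 genes changed 4-fold the shares without the set were 83.3%, 84.8%, 87.9%, 86.4%, 84.8% and 62.1% in the same order. A simulated 1.5-fold rise of the cholesterol synthesis list between TKO and control gave a fry adjusted p of 3.8e-06, with 0 of 28 other lists called. Genes were simulated independently, while members of a list can vary together between real livers. The simulation therefore does not give the power or the rate of false list calls in these data. In the real fit that list had a median log2 of -0.75 and did not pass (fry adjusted p = 0.109). Set differences of the fitted size, simulated with no group difference in the 395 genes called for the set, gave 0 calls in each comparison. After the data were seen this was repeated with the spread of the fit that holds the set, in those genes and in all genes, with 0 calls again.

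The comparisons, the gene lists, the naming rule and the first alternatives were fixed before the data were examined. The rule named the 3 deleted genes. It also named, per comparison, up to 10 rises and 10 falls with the largest change among genes called, with a mean of at least 5 CPM in the higher group and no overlap between groups (all 4 groups and no overlap condition for the interaction). Model and clone names, immunoglobulin and T cell receptor segments and pseudogenes were left out. Last, it named up to 4 members of each list with the smallest adjusted p.

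The 30 lists held 546 genes, 471 of them tested. They covered DNA replication and S phase, G2 and mitosis, E2F, RB and G1 cyclins, fatty acid synthesis, lipid droplet and PPARG targets, cholesterol synthesis, fatty acid oxidation and ketogenesis, gluconeogenesis and FOXO targets, glycolysis, bile acid synthesis and transport, hepatocyte function, NRF2 and xenobiotic response, cholangiocyte markers, oncofetal and liver tumor markers, stellate cell and matrix genes, Kupffer cell and macrophage markers, neutrophil markers, T and NK cell markers, B and plasma cell markers, sinusoidal endothelial markers, red blood cell genes, pancreatic acinar genes, acute phase and cytokine genes, interferon response, p53 targets, ER stress and ATF4 targets, male-biased and female-biased liver genes, circadian clock genes, and immediate early and heat shock genes. Pancreatic acinar genes had 2 of 11 members measured, fewer than the 3 required, and were not tested. Lists were tested with limma's fry on log2 CPM (prior count 2), adjusted over the lists of a comparison. That test asks whether a list's genes moved one way on balance and does not compare them with other genes. Camera was run with a preset correlation of 0.01 and with an estimated correlation, and with the latter 0 lists were called in any comparison, nor with the library set or without E2f78DKO 3 and PtenKO 3.

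Alternatives were DESeq2, limma-voom with quality weights, RLE factors, no filter or a mean of at least 5 CPM, only the groups compared, the replicate number as a block, the letter of the sample code as a covariate, a minimum fold of 1.5, and each library left out. After the data were seen, the library set was added as a covariate. It was read from the first principal component of annotated pseudogenes. Fits of the larger set only, without E2f78DKO 3 and PtenKO 3, and of protein-coding genes only were added at the same stage.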

Results

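Gene expression was measured by poly(A) RNA sequencing of whole liver pieces from 16 mice, all 16 weeks old, in 4 groups of 4 libraries. The labels give the groups as Alb-Cre controls, E2f78DKO for loss of E2f7 and E2f8, PtenKO for loss of Pten, and TKO for loss of all 3 genes. Alb-Cre is a recombinase driven by the albumin promoter, which is active in hepatocytes. E2f7 and E2f8 are the atypical E2F transcription factors, repressors of E2F target genes, and Pten is the lipid phosphatase that opposes PI3K signalling. The design text, unlike the labels, calls the E2f78DKO samples liver tumors and the controls wild-type, and which holds is not known here. The series title names the study's subject as deletion of both kinds of gene in liver. The libraries held 23872002 to 61966456 counts in controls, 23038691 to 28924266 in E2f78DKO, 19940022 to 21381674 in PtenKO and 18557270 to 29690615 in TKO. All 16 libraries carried Y-linked Ddx3y at 59.4 to 89.6 CPM (counts scaled to library size) and Xist at no more than 0.564 CPM. Levels below are CPM as mean ± SD of 4 libraries, and differences are log2 fold changes ± standard error from 1 fit of all 16 libraries, with adjusted p from edgeR.

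Pten (chromosome 19, 32757497 to 32826160, GRCm38) stood at 150 ± 22.6 CPM in controls, 167 ± 37.6 in E2f78DKO, 71.7 ± 5.55 in PtenKO and 93.1 ± 17.1 in TKO libraries. It was lower by a log2 of -1.06 ± 0.17 in PtenKO than in controls (adjusted p = 0.00199), but with the library set described below in the model the difference was -0.74 ± 0.19 and the call was lost (adjusted p = 0.118). It was lower by -0.84 ± 0.17 in TKO than in E2f78DKO (adjusted p = 0.0125, 0.0208 with the set, and 0.0533 without TKO 3). Against controls the TKO difference was -0.69 ± 0.17 (adjusted p = 0.0605, and 0.0328 with the set). With the letter of the sample code as a covariate none of these 3 differences passed (adjusted p = 0.236, 1 and 1). E2f7 (chromosome 10, 110745439 to 110787384) was low everywhere, at 0.756 ± 0.572 CPM in controls, 0.879 ± 0.478 in E2f78DKO, 3.01 ± 0.957 in PtenKO and 0.551 ± 0.355 in TKO. E2f8 (chromosome 7, 48866429 to 48881596) went against the labels: it held 5.81 ± 3.96 CPM in controls and 6.11 ± 1.34 in PtenKO, but 41.6 ± 32.2 in the libraries labelled E2f78DKO and 52.3 ± 30.9 in those labelled TKO. Counts of a whole gene can include exons that a deletion leaves in place, and which exons were removed is not given in the sources used here. Gm2788, an antisense gene at 48877958 to 48913040 on chromosome 7 that overlaps E2f8, was at 13.1 ± 4.26 CPM in controls, 25.1 ± 8.88 in PtenKO, 0.438 ± 0.312 in the libraries labelled E2f78DKO and 0.559 ± 0.279 in those labelled TKO. Gm2788 was chosen after its values were seen. Without a stated strand setting, its reads cannot be told apart from those of E2f8 where both genes overlap (48877958 to 48881596). No library labelled E2f78DKO or TKO lay within the range of the other 8 for Gm2788. Group names in all that follows stand for libraries labelled so, since E2f8 counts did not fall with the label.

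**Figure D1:**
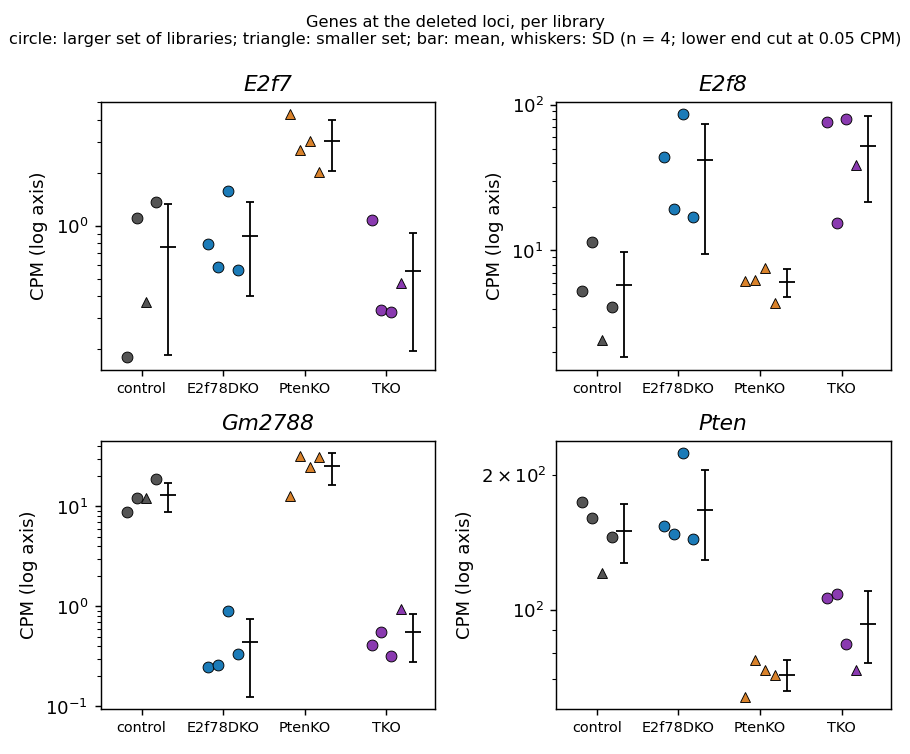
CPM on a log axis of E2f7, E2f8, Gm2788 and Pten in each of the 16 libraries by labelled group, with the mean and SD (n = 4) beside each group. The 8 libraries labelled E2f78DKO or TKO lie above the other 8 for E2f8 and below them for Gm2788.

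The libraries also fell into 2 sets that were not the genotype groups. The first principal component of 1789 pseudogenes, which carried 56.7% of their variance, parted control 3, PtenKO 1 to 4 and TKO 4 from the other 10 libraries. Pseudogenes held 5.65% to 7.39% of the counts in these 6 libraries and 8.04% to 10.4% in the other 10. Depth differed too, at 18557270 (TKO 4) to 23872002 (control 3) counts in the 6, where the other 10 held at least 23038691 (E2f78DKO 3). Lars2, a mitochondrial leucyl-tRNA synthetase gene, ran at 663 to 1148 CPM in these 6 libraries and at 19.6 to 82.1 in the other 10, and Rps10, a ribosomal protein gene, at 0.580 to 1.10 against 6.40 to 39.2 (Lars2 was chosen after its values were seen). With the set added to the fit, 395 genes differed between the sets, 143 of them protein-coding and 235 pseudogenes, the class that defined the sets. These were 1.15% of the protein-coding genes and 13.1% of the pseudogenes tested. Since every PtenKO library was in the smaller set, only control 3 and TKO 4 separate set from genotype in comparisons with PtenKO, and the total of each comparison is given both without and with the set. Separately, E2f78DKO 3 and PtenKO 3 had high acute-phase genes: Saa1, a serum amyloid A gene, stood at 6871 and 20687 CPM there and at 16.6 to 723 in the other 14 libraries, and Lcn2, or lipocalin 2, at 1293 and 2838 against 2.28 to 72.5. Saa1 and Lcn2 were also chosen after their values were seen.

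**Figure D2:**
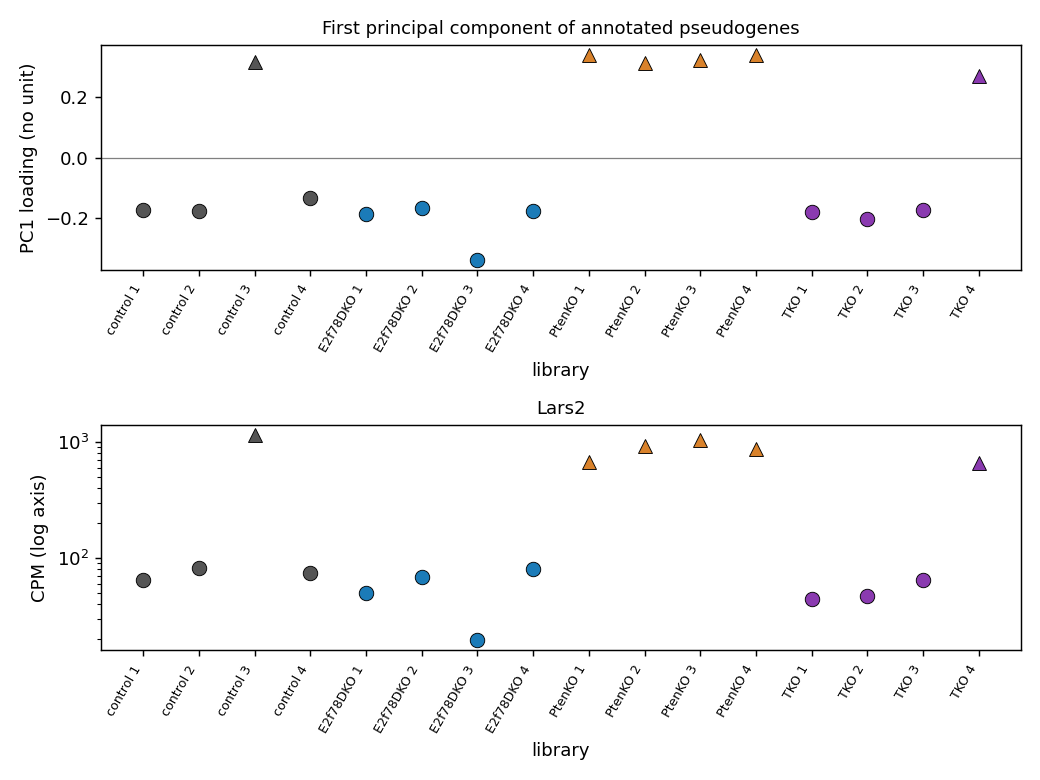
First principal component of annotated pseudogenes (no unit) and Lars2 in CPM on a log axis for each of the 16 libraries, coloured by labelled group, with triangles for the smaller set and circles for the larger. Control 3, TKO 4 and the 4 PtenKO libraries lie apart from the other 10 on both.

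The first comparison set the libraries labelled E2f78DKO against controls. Dclre1a, a DNA cross-link repair nuclease, was lower in the libraries labelled E2f78DKO, at 10.8 ± 1.49 CPM against 21.7 ± 1.98 in controls (log2 -1.01 ± 0.16, adjusted p = 0.0440), and Gm2788 was lower by -5.00 ± 0.44 (adjusted p = 5.1e-05). E2f8 itself differed by 2.83 ± 0.63 without passing the threshold (adjusted p = 0.376). Of the 33 G2 and mitosis genes measured, 0 passed over all genes and 14 were higher when adjusted over the list alone. All 33 had a positive log2 difference, with a median of 1.25, and the list as a whole did not pass (fry adjusted p = 0.104). It did once E2f78DKO 3 and PtenKO 3 were left out, with 21 higher adjusted over the list alone (fry adjusted p = 0.0468, and 0.172 with an estimated correlation). That fit was chosen after the data were seen. E2f78DKO 3 had the lowest mean log2 CPM of this list in its group (-0.665, against -0.367 to 0.315), though above all 4 controls. Among the G2 and mitosis genes, with all libraries, Ccna2, or cyclin A2, differed by 2.46 ± 0.53 (adjusted p = 0.287), Prc1, a spindle midzone protein, by 2.82 ± 0.66 (adjusted p = 0.376) and the mitotic kinase Aurkb by 1.94 ± 0.55 (adjusted p = 0.425). Of 47 DNA replication and S phase genes 0 passed over all genes and 1 was higher adjusted over the list alone (median log2 0.25, fry adjusted p = 0.533). The interferon response list had 0 of 17 called and 7 higher adjusted over the list alone, with a median of 0.75 (fry adjusted p = 0.104). With the library set it passed (fry adjusted p = 0.0308, and 0.0905 with an estimated correlation in that fit). Irf7, an interferon regulatory factor, differed by 0.94 ± 0.25 and Ifit1, an interferon-induced antiviral gene, by 0.86 ± 0.24, both short of the threshold over all genes. Of 4 neutrophil markers 0 were called and 3 were higher adjusted over the list alone (median log2 2.63, fry adjusted p = 0.208). Of 12 acute-phase and cytokine genes 0 were called by either count (median log2 2.17, fry adjusted p = 0.356), and Saa1 and Lcn2 were highest in E2f78DKO 3. With E2f78DKO 3 and PtenKO 3 left out the median of the acute-phase list was 0.90, with 7 higher adjusted over the list alone (fry adjusted p = 0.133). That of the neutrophil markers was 1.505, with 3 higher adjusted over the list alone, and that list then passed (fry adjusted p = 0.0209, and 0.0815 with an estimated correlation). So did the 13 ER stress and ATF4 targets, with a median of 0.75 and 0 called by either count (fry adjusted p = 0.0288, and 0.0815 with an estimated correlation), against 0.104 with all libraries. E2f78DKO 2 and 4 also lay above all 4 controls, at 196 and 723 CPM against up to 185 for Saa1 and at 18.4 and 72.5 against up to 9.47 for Lcn2.

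In all, 2 of 14844 genes passed an adjusted p of 0.05 in edgeR, both lower, while 1426 had an unadjusted p under 0.05. DESeq2 called 22 genes and limma-voom 38. With the library set in the model the count was 1, in the larger set alone 1, with the letter of the sample code as a covariate 1, and without E2f78DKO 3 and PtenKO 3 it was 5. Only the Gm2788 call held whichever library was left out, and Dclre1a kept its call in 4 of the 16 such fits.

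The next comparison set the PtenKO libraries against controls. Several genes of lipid storage were higher in PtenKO. Cidea, a lipid droplet protein, stood at 8.90 ± 9.38 CPM in PtenKO and at 0.0172 ± 0.0248 in controls, where its counts were near 0. The lipid droplet lipase Pnpla3 rose by a log2 of 5.83 ± 1.07 (adjusted p = 0.00818), the acyltransferase Mogat1 by 5.03 ± 0.80 (adjusted p = 0.00277), the lipid droplet protein Cidec by 4.82 ± 0.89 (adjusted p = 0.00858) and Pparg, a nuclear receptor of fat storage, by 2.22 ± 0.42 (adjusted p = 0.00778). Of the 14 lipid droplet and PPARG targets 7 rose and 1 fell, against 8 and 1 adjusted over the list alone (median log2 1.01, fry adjusted p = 0.0178, and 0.266 with an estimated correlation). The member that fell was Lpl, or lipoprotein lipase, at -1.14 ± 0.25 (adjusted p = 0.0146), named after its value was seen. Of 23 fatty acid synthesis genes 2 rose, Pnpla3 and the glucokinase gene Gck at 1.13 ± 0.30, and 3 did so adjusted over the list alone (median log2 0.67, fry adjusted p = 0.190). In the fit without E2f78DKO 3 and PtenKO 3, 6 rose and 11 did so adjusted over the list alone, and the list passed (median log2 0.77, fry adjusted p = 0.0176, and 0.325 with an estimated correlation). That fit was chosen after the data were seen. It left out the lowest PtenKO library for this list, PtenKO 3, whose mean log2 CPM of 6.88 lay within the controls (6.74 to 7.45). The other PtenKO libraries stood at 7.78 to 8.38.

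Other genes with large rises were Pls1, an actin-bundling plastin, at 4.21 ± 0.35, Nipal2 at 5.18 ± 0.40, Fam83a at 4.46 ± 0.45, Gnai1, an inhibitory G protein subunit, at 4.04 ± 0.40, and Ifi27l2b at 3.88 ± 0.49. Apoa4, an apolipoprotein, went from 68.1 ± 30.5 to 637 ± 201 CPM, a 9.35-fold rise. Among the falls were 3 cytochrome P450 genes of the Cyp2c family: Cyp2c54 was lower by -4.27 ± 0.59, Cyp2c37 by -4.08 ± 0.58 and Cyp2c50 by -3.53 ± 0.43. These are near-identical neighbours, so reads could be split between them in counting. Igfbp2, a binding protein of insulin-like growth factors, was lower by -4.20 ± 0.67, from 187 ± 14.9 to 10.1 ± 4.89 CPM, the zinc importer Slc39a4 from 37.0 ± 8.58 to 4.15 ± 2.59, and the kynurenine aminotransferase gene Kyat3 from 129 ± 29.1 to 30.4 ± 15.3. Irs2, an insulin receptor substrate, fell by 2.15 on the log2 scale, Pde4b, a cyclic AMP phosphodiesterase, by 2.23, and Susd4, a regulator of complement, by 2.19. All of these genes from Pls1 to Susd4 had adjusted p from 2.5e-06 (Nipal2) to 0.00847 (Irs2). The mitochondrial gene mt-Nd4l was also lower (-2.52 ± 0.59, adjusted p = 0.0234), but by only -0.67 with the library set in the model (adjusted p = 0.818).

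Hepatocyte function genes were lower as a list, with 5 of 26 down and 0 up, against 11 down and 1 up adjusted over the list alone (median log2 -0.29, fry adjusted p = 0.000627, 0.00760 with the library set, and 0.0716 with an estimated correlation). They included Cyp2e1 at -0.98 ± 0.19, Cyp1a2 at -1.07 ± 0.29 and the urea cycle enzyme Cps1 at -0.77 ± 0.18. Of 19 p53 targets 4 rose and 0 fell, against 6 and 0 adjusted over the list alone (median log2 0.50, fry adjusted p = 0.000627, 0.00942 with the library set, and 0.0716 with an estimated correlation). Those 4 were the cell cycle inhibitor Cdkn1a at 3.08 ± 0.53, the death receptor Eda2r at 2.02 ± 0.45, cyclin G1 (Ccng1) at 0.61 ± 0.14 and the antiproliferative gene Btg2 at 1.64 ± 0.46. With the library set 0 of the 26 hepatocyte genes, 0 of the 19 p53 targets and 1 of the 14 lipid droplet genes, Pparg, were called. The hepatocyte function and p53 list calls also held whichever library was left out, unlike the other 8 list calls of this comparison, which were each called in 9 to 14 of the 16 such fits and all lost without control 2. Of 13 ER stress and ATF4 targets 3 rose, Atf3, Psat1 and Ddit4, and 5 did so adjusted over the list alone (fry adjusted p = 0.0238, and 0.266 with an estimated correlation). Of 8 oncofetal genes Afp, or alpha-fetoprotein, rose (1.14 ± 0.18) and Akr1c18, a hydroxysteroid dehydrogenase, fell (-1.19 ± 0.32), with 3 up and 1 down adjusted over the list alone (fry adjusted p = 0.0238, and 0.359 with an estimated correlation). The median of that list went from 1.05 to 0.39 without E2f78DKO 3 and PtenKO 3, and the call was lost (fry adjusted p = 0.123). Ighm, the IgM heavy chain, was the 1 of 5 B and plasma cell markers to rise (1.67 ± 0.26), with 3 adjusted over the list alone (fry adjusted p = 0.0152, and 0.266 with an estimated correlation). Without the same 2 libraries 1 rose by either count and this list call was lost too (median log2 0.58 against 0.95, fry adjusted p = 0.0561). Of 6 red blood cell genes 3 rose, Alas2, Hbb-bt and Slc4a1, and 3 adjusted over the list alone (fry adjusted p = 0.0152, and 0.266 with an estimated correlation). Btg2, Ddit4 and Slc4a1 were highest in PtenKO 3 and lost their calls without it (adjusted p = 0.148, 0.171 and 0.0941).

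Of 15 gluconeogenesis and FOXO targets 1 was lower, Irs2, and 1 adjusted over the list alone (fry adjusted p = 0.0353, and 0.268 with an estimated correlation). Of 15 circadian clock genes 0 were called either way, with a median of -0.31 (fry adjusted p = 0.0353, and 0.268 with an estimated correlation). Of 18 E2F, RB and G1 cyclin genes cyclin D2 (Ccnd2) was lower by -0.62 ± 0.15, and 2 were lower adjusted over the list alone (fry adjusted p = 0.0238, and 0.266 with an estimated correlation). Of these 8 further list calls none remained with the library set, with adjusted p from 0.0949 to 0.238. E2f7 rose by 1.94 ± 0.52 (adjusted p = 0.0383, and 0.256 with the set). Among replication genes Rrm2, a subunit of ribonucleotide reductase, rose by 1.36 ± 0.28 (adjusted p = 0.00990). That list had 1 of 47 higher over all genes and 1 adjusted over the list alone (fry adjusted p = 0.307). Without E2f78DKO 3 and PtenKO 3 it had 5 higher by either count (fry adjusted p = 0.376). Of 33 G2 and mitosis genes 32 had a positive log2 difference, 1 was called and 0 adjusted over the list alone (median log2 0.68, fry adjusted p = 0.268). Without the same 2 libraries 26 were positive, with 1 called and 0 adjusted over the list alone (median log2 0.30, fry adjusted p = 0.618). Of 4 neutrophil markers 0 were called and 2 were higher adjusted over the list alone (median log2 3.10, fry adjusted p = 0.179). Their median was 0.81 without E2f78DKO 3 and PtenKO 3, where 2 rose by either count and the list passed (fry adjusted p = 0.0367, and 0.325 with an estimated correlation). Of 12 acute-phase and cytokine genes 0 were called and 5 were higher adjusted over the list alone (median log2 1.90, fry adjusted p = 0.505), and without those 2 libraries the median was -0.06, with 1 lower by either count (fry adjusted p = 0.983).

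In all, 858 of 14844 genes differed between PtenKO and control, 426 higher and 432 lower, and 700 of them had no overlap between the 4 libraries of each group. With the library set in the model 64 passed, 42 higher and 22 lower. Of the 858, 848 kept their sign in that fit, and the median size went from 1.15 to 0.85 while the median standard error went from 0.26 to 0.33. The genes named above that passed with the set were Nipal2, Fam83a, Pls1, Gnai1, Ifi27l2b, Apoa4, Pparg, the 3 Cyp2c genes, Igfbp2, Slc39a4, Susd4 and Kyat3. With the code letter as a covariate 47 passed. Without E2f78DKO 3 and PtenKO 3 the count was 1495, and 230 with the set as well. The count ran from 301 without control 2 to 1740 without E2f78DKO 3, and stood at 391, 1682 and 438 without control 1, 3 and 4, and at 470 and 455 without PtenKO 1 and 4. Of 55 genes looked up here with a call, Lpl among them, 31 kept it whichever library was left out.

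**Figure D3:**
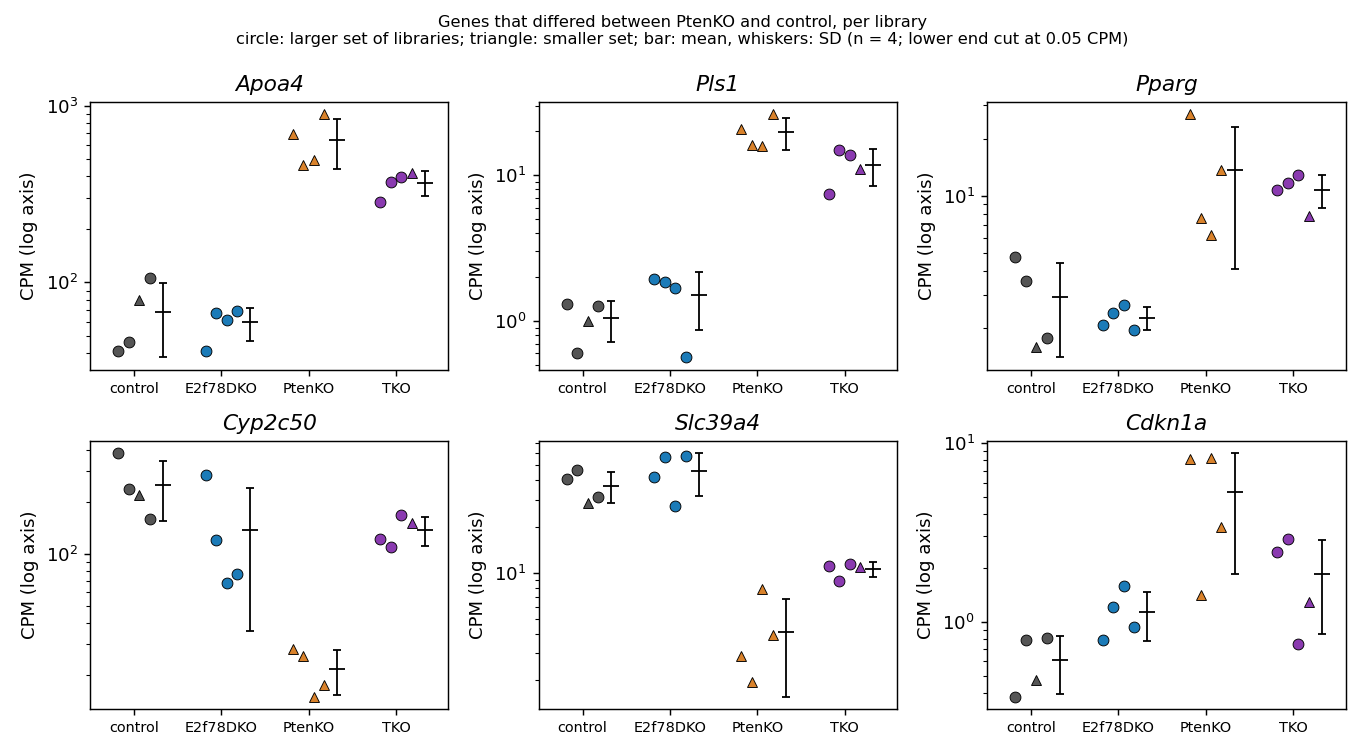
CPM on a log axis of 6 genes that differed between PtenKO and control, in each of the 16 libraries by labelled group, with the mean and SD (n = 4) beside each group and triangles for the smaller library set. Apoa4, Pls1 and Pparg are higher, and Cyp2c50 and Slc39a4 lower, in the 4 PtenKO libraries than in the 4 controls, with Cdkn1a at 5.30 ± 3.45 against 0.615 ± 0.220 CPM.

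The libraries labelled TKO were compared with controls next. In them Pls1 was 11.1-fold higher than in controls (adjusted p = 5.8e-05), Aqp8, a water channel, went from 10.2 ± 4.19 to 80.3 ± 18.9 CPM, and Apoa4 from 68.1 ± 30.5 to 366 ± 57.9. Pik3c2g, a class II PI3-kinase, rose by 2.81 ± 0.40, Ntrk2, the BDNF receptor TrkB, by 2.39 ± 0.32, Adgrv1, an adhesion G protein-coupled receptor, by 2.50 ± 0.41, and Slc2a4, the insulin-regulated glucose transporter GLUT4, by 2.98 ± 0.64. E2f8 counts were also higher (3.16 ± 0.63, adjusted p = 0.0270), against the label. Gm2788 was lower by -4.58 (adjusted p = 4.7e-05). Among genes that the naming rule allows, falls were led by A2ml1, a protease inhibitor of the alpha-2-macroglobulin family, at -3.45 ± 0.59 and Mmd2 at -3.09 ± 0.30. The sphingosine-1-phosphate receptor S1pr5 followed at -2.41 ± 0.20 and the adhesion receptor Adgrf1 at -2.38 ± 0.38. Oat, or ornithine aminotransferase, went from 483 ± 153 to 113 ± 12.1 CPM, Kyat3 from 129 ± 29.1 to 28.7 ± 1.92 and Acmsd, of tryptophan catabolism, from 33.3 ± 11.7 to 8.51 ± 1.53. Oat-rs1 fell by 2.08, and as a sequence related to Oat it can share its reads. The ER protein Derl3 fell by 2.21 and cyclin D1 (Ccnd1) by 1.93, the latter with an adjusted p of 0.0446.

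Of 21 cholesterol synthesis genes 4 fell, Msmo1 at -1.57 ± 0.30, Sqle at -1.69 ± 0.36, Idi1 at -1.72 ± 0.38 and Lss at -1.13 ± 0.26, and 9 fell adjusted over the list alone. The median of the list was -0.75 and the list did not pass (fry adjusted p = 0.109). Of 14 lipid droplet and PPARG targets only Pparg rose over all genes (1.87 ± 0.42, adjusted p = 0.0404), with 6 higher and 1 lower adjusted over the list alone (median log2 1.13, fry adjusted p = 0.0869). That list passed without E2f78DKO 3 and PtenKO 3, with 5 up over all genes and 9 higher and 1 lower adjusted over the list alone (fry adjusted p = 0.0380, and 0.434 with an estimated correlation). The chaperone gene Hspa5 was lower (-1.07 ± 0.21, adjusted p = 0.0173), the 1 of 13 ER stress and ATF4 targets to pass, while adjusted over the list alone 2 were higher and 1 lower (fry adjusted p = 0.589). Marco, a scavenger receptor of macrophages, was lower (-2.92 ± 0.54, adjusted p = 0.0144), the 1 of 17 Kupffer cell and macrophage markers to pass by either count (fry adjusted p = 0.449). Ighm was higher (1.79 ± 0.26, adjusted p = 0.00212), the 1 of 5 B and plasma cell markers to pass by either count (fry adjusted p = 0.109). Hepatocyte function genes were the 1 list that passed, downward, with 0 of 26 called and 1 lower adjusted over the list alone (median log2 -0.21, fry adjusted p = 0.0412, 0.0491 with the library set, and 0.207 with an estimated correlation). That call was lost without E2f78DKO 3 and PtenKO 3 (fry adjusted p = 0.0593) and with the code letter (0.853), and it held in only 4 of the 16 fits that left out a library, those without E2f78DKO 1 or 2, PtenKO 3 or TKO 3, with up to 0.176 without control 3. G2 and mitosis genes had 0 of 33 called and 2 higher adjusted over the list alone (median log2 0.86, fry adjusted p = 0.210). Without E2f78DKO 3 and PtenKO 3 they had 1 called and 10 higher adjusted over the list alone (median log2 0.84, fry adjusted p = 0.128).

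In all, 145 genes differed, 75 higher and 70 lower, and 163 did with the library set in the model, 141 of them in both. All 4 TKO libraries carry the code letter b, which no control does, and only PtenKO 1 links that letter to the others. With the letter as a covariate edgeR called 0 genes, with 584 at an unadjusted p under 0.05. Of the 145, 143 kept their sign there, and their median standard error went from 0.29 to 0.54. In the larger set alone, with 3 libraries a group, 69 passed, and without E2f78DKO 3 and PtenKO 3 the count was 445 (601 with the set as well). The count ran from 65 without TKO 2 to 285 without E2f78DKO 3, and was 95, 92 and 85 without control 1, 2 and 3, 222 without PtenKO 3, and 78 and 94 without TKO 3 and 4. Of 29 such genes, Gm2788 among them, 16 kept it whichever library was left out and 27 kept it with the set, with Ccnd1 (adjusted p = 0.0577) and Lss (0.0559) the exceptions.

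The libraries labelled TKO were then set against those labelled PtenKO. In TKO 10 of 21 cholesterol synthesis genes fell, 0 rose and 11 were not called, and 12 fell adjusted over the list alone. Sqle went from 140 ± 74.8 to 33.2 ± 13.0 CPM (log2 -2.08 ± 0.37, adjusted p = 0.00885), Idi1 fell by 1.93, Fdps by 2.06 and Lss by 1.04. The list did not pass (median log2 -1.01, fry adjusted p = 0.107), and with the library set 0 of the 21 were called while the median stayed at -1.01. Without E2f78DKO 3 and PtenKO 3, 6 of the 21 fell, and 11 adjusted over the list alone (median log2 -0.88, fry adjusted p = 0.131). Of 13 ER stress and ATF4 targets 4 fell over all genes and 4 adjusted over the list alone. Those of the first count were Asns, or asparagine synthetase, at -3.82 ± 0.69 (adjusted p = 0.0102), Hspa5 at -0.86 ± 0.21, Atf3 at -1.45 ± 0.35 and Ddit4 at -1.88 ± 0.49. That list passed (fry adjusted p = 0.0299, 0.148 with the library set, and 0.835 with an estimated correlation), with 0 of the 13 called once the set was in the model. The list call was lost without E2f78DKO 2, PtenKO 3, TKO 2 or TKO 4 (fry adjusted p = 0.0527, 0.0636, 0.0541 and 0.106). Without PtenKO 3 the Ddit4 difference was -0.92 (adjusted p = 0.0847), and without TKO 3 Hspa5 and Atf3 lost their calls (adjusted p = 0.0784 and 0.0723). Of 17 Kupffer cell and macrophage markers 0 had a positive difference, 2 fell and 6 were lower adjusted over the list alone (median log2 -0.63, fry adjusted p = 0.166). Of 12 acute-phase and cytokine genes 0 were called and 7 were lower adjusted over the list alone (median log2 -2.71, fry adjusted p = 0.520). Without E2f78DKO 3 and PtenKO 3 these medians were -0.34 and -0.46, and the ER stress list had an adjusted p of 0.0345.

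Several genes that were high in PtenKO stood lower in TKO. Nipal2 went from 8.65 ± 3.06 to 0.779 ± 0.115 CPM, Fam83a from 8.48 ± 4.67 to 1.37 ± 0.738, Rims4 from 15.2 ± 7.23 to 1.89 ± 1.19 and Ifi27l2b from 5.95 ± 3.42 to 0.864 ± 0.408. Cidea was also lower, at 0.601 ± 0.278 CPM, a log2 difference of -3.91 ± 0.83 (adjusted p = 0.0166). The Cyp2c genes were higher in TKO, Cyp2c50 at 137 ± 26.8 against 21.5 ± 6.31 CPM, Cyp2c54 by 2.93 ± 0.56 and Cyp2c37 by 3.03 ± 0.56. Other falls were A2ml1 at -4.10 ± 0.60, Mmd2 at -3.19 ± 0.31, Marco at -3.66 ± 0.55 and the ferritin receptor Scara5 at -2.81 ± 0.66. Trat1, a T cell receptor adaptor, held 11.9 ± 22.9 CPM in PtenKO and 0.0171 ± 0.0199 in TKO, near 0, and lost its call without PtenKO 3 (adjusted p = 0.146). Cd3e, a T cell marker, rose by 2.19 ± 0.46, the 1 of 6 T and NK cell markers to pass over all genes, with 1 higher and 1 lower adjusted over the list alone (fry adjusted p = 0.641). Cux2, a female-biased liver gene, rose by 3.13 ± 0.66 from 0.102 ± 0.0462 CPM, the 1 of 10 in its list to pass by either count (fry adjusted p = 0.966). E2f7 was lower (-2.42 ± 0.55, adjusted p = 0.0195, and 0.232 with the set), and E2f8 counts higher (3.10 ± 0.64, adjusted p = 0.0162, and 0.305 with the set), against the label.

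The largest rises included genes that followed the library set. Scand1, Rps10, the translationally controlled Tpt1, Zfp771, Tpgs1 and Rab43 rose by 5.48, 3.53, 3.08, 2.42, 2.17 and 2.15 on the log2 scale, and with the set in the model their differences were 1.96, 0.23, 0.76, 0.85, 0.84 and 1.20, none of them called. Over all genes 1248 differed, 667 higher and 581 lower, 193 of them pseudogenes, and with the set 16 did, 8 each way. Of the 1248, 1224 kept their sign with the set, and the median size went from 0.87 to 0.60 while the median standard error went from 0.21 to 0.26. Of the genes named here Nipal2, Mmd2 and Cux2 kept the call both with the set and in all 16 fits that left out a library, as did Gm2788 (-5.53 ± 0.43, adjusted p = 8.6e-06). With the code letter as a covariate 28 passed. Without E2f78DKO 3 and PtenKO 3 the count was 1949, and 74 with the set as well. The count ran from 303 without TKO 3 to 2409 without E2f78DKO 3, and was 628, 519, 532 and 461 without PtenKO 1, 2, 3 and 4, and 421 and 460 without TKO 1 and 2. Of 51 genes looked up with a call, Gm2788 among them, 23 kept it whichever library was left out and 4 with the set.

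**Figure D4:**
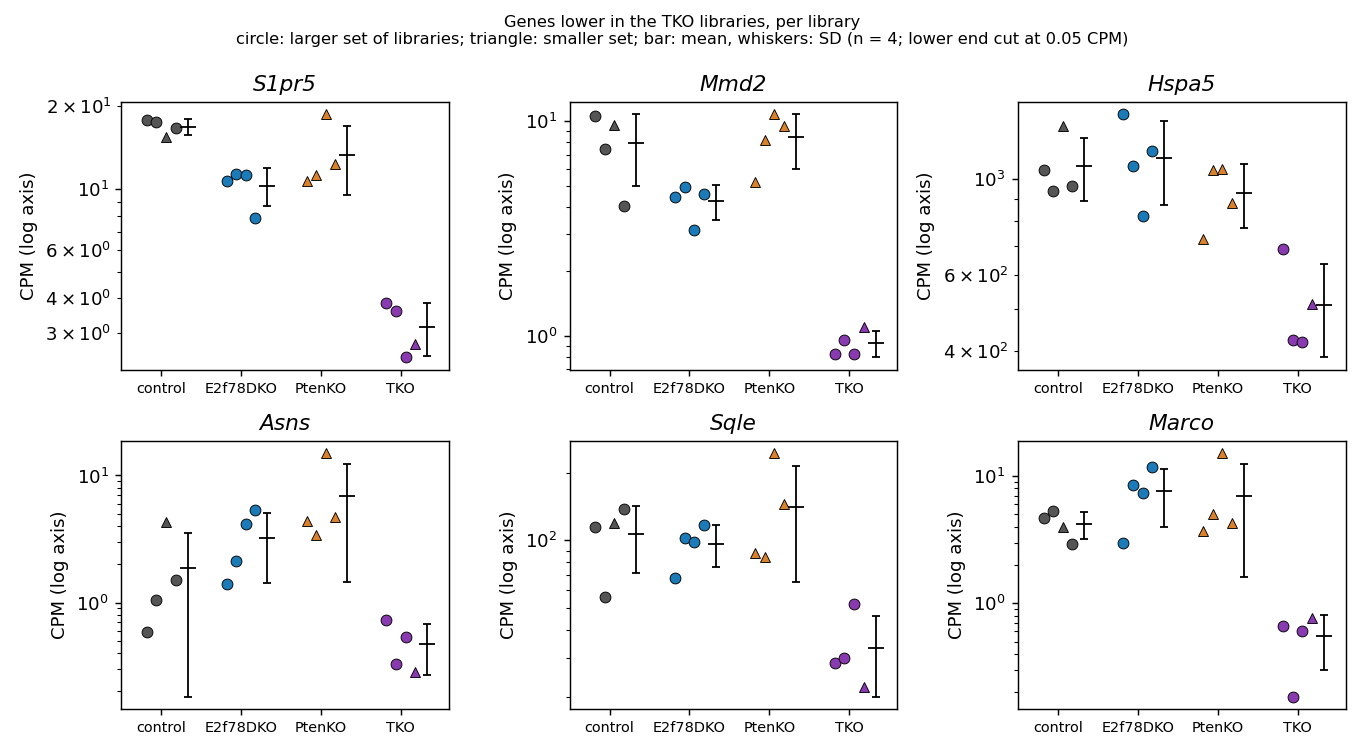
CPM on a log axis of 6 genes that were lower in the TKO libraries than in PtenKO or control, in each of the 16 libraries by labelled group, with the mean and SD (n = 4) beside each group and triangles for the smaller library set. S1pr5 and Mmd2 lie lower in the 4 TKO libraries than in the 12 others, with Mmd2 at 0.925 ± 0.131 CPM in TKO and 8.43 ± 2.40 in PtenKO.

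The libraries labelled TKO were also set against those labelled E2f78DKO. Among genes higher in TKO, Pik3c2g went from 1.39 ± 0.548 to 26.2 ± 6.13 CPM (adjusted p = 0.000322), Ntrk2 from 12.5 ± 3.27 to 127 ± 18.9, Acss3, an acyl-CoA synthetase, from 2.06 ± 0.204 to 25.7 ± 8.31, and Aqp8 from 10.6 ± 5.87 to 80.3 ± 18.9. Pls1 rose by 2.96 ± 0.34, the calsyntenin Clstn3 by 3.40 ± 0.61, Slc2a4 by 3.12 ± 0.66, the kinase Aatk by 2.82 ± 0.46 and Nat8f7 by 2.88 ± 0.59. C1s2, a complement protease gene with a near-identical copy, was at 0.00893 ± 0.0179 CPM in E2f78DKO, near 0, and at 12.4 ± 1.83 in TKO. Among controls it stood at 9.78 CPM in control 3 and at 0 in the others, so it also varied without a labelled deletion. Among genes that the naming rule allows, falls were led by A2ml1 at -4.89 ± 0.62 and Marco at -3.79 ± 0.55. Cfhr1, a complement factor H relative, fell by 3.62 and Clec2h, of a C-type lectin family, by 2.86, and both can share reads with their relatives. Lrp2, or megalin, fell by 2.37, Adgrf1 by 2.49, Kyat3 by 2.29, Nucb2 by 2.16, Slc39a4 by 2.11 and Scara5 by 2.59 (adjusted p = 0.0496).

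Of 14 lipid droplet and PPARG targets Pparg rose by 2.25 ± 0.43 and Mogat1 by 4.36 ± 0.94, and 10 were higher and 1 lower adjusted over the list alone (median log2 1.42, fry adjusted p = 0.0544). Of 23 fatty acid synthesis genes Gck rose (1.31 ± 0.31), with 9 higher adjusted over the list alone (median log2 0.78, fry adjusted p = 0.179). Of 21 cholesterol synthesis genes 4 fell, Cyp51, Sqle, Idi1 and Msmo1, and 6 adjusted over the list alone (median log2 -0.51, fry adjusted p = 0.206). Of 13 ER stress and ATF4 targets Hspa5 fell by 1.13, Dnajb9 by 1.46 and Asns by 2.74, and 4 fell adjusted over the list alone (median log2 -0.39, fry adjusted p = 0.0510). Of 17 Kupffer cell and macrophage markers 3 fell, Marco, Timd4 at -1.06 ± 0.24 and Vsig4 at -1.03 ± 0.24, and 11 adjusted over the list alone (median log2 -0.59, fry adjusted p = 0.0993). Pten fell by 0.84, and Afp rose by 0.91 ± 0.18, the 1 of 8 oncofetal genes to pass by either count (fry adjusted p = 0.206). With fry 0 of 29 lists passed with all libraries and 4 did without E2f78DKO 3 and PtenKO 3. Those 4 were lipid droplet and PPARG targets, with 6 up (fry adjusted p = 0.0288), ER stress and ATF4 targets, with 4 down (0.0169), Kupffer cell and macrophage markers, with 5 down (0.0458), and E2F, RB and G1 cyclin genes, with 1 of 18 down (0.0458). Adjusted over the list alone these were 9 up and 1 down, 1 up and 6 down, 11 down, and 1 up and 3 down, and with an estimated correlation each of the 4 lists had an adjusted p of 0.411. In the same fit without 2 libraries 2 of 12 acute-phase and cytokine genes fell, and 6 adjusted over the list alone (median log2 -1.53, fry adjusted p = 0.0590). Of 17 interferon response genes 3 fell, with 1 higher and 6 lower adjusted over the list alone (median log2 -0.48, fry adjusted p = 0.187). Of 4 neutrophil markers 0 were called and 1 was lower adjusted over the list alone (median log2 -0.62, fry adjusted p = 0.158). With all libraries camera with a preset correlation called 8 and with an estimated correlation 0.

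In all, 421 genes differed, 202 higher and 219 lower, and 281 did with the library set in the model, 262 of them in both. The TKO libraries all carry the code letter b and the E2f78DKO libraries p or q. With the letter as a covariate edgeR called 0 genes, with 469 at an unadjusted p under 0.05. Of the 421, 409 kept their sign there, and their median standard error went from 0.22 to 0.49. In the larger set alone 160 passed, and without E2f78DKO 3 and PtenKO 3 the count was 690 (701 with the set as well). The count ran from 169 without TKO 3 to 746 without PtenKO 3, and was 192 without E2f78DKO 4 and 173 and 212 without TKO 2 and 4. Of 40 named genes with a call, 18 kept it whichever library was left out and 28 kept it with the set.

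The interaction term asked whether the difference between TKO and PtenKO was another than that between E2f78DKO and control, by label. Genes with a lower value in TKO than the separate differences gave were A2ml1 (-5.54 ± 0.79, adjusted p = 0.0229), Scara5 (-4.81 ± 0.91), Asns (-4.68 ± 0.92), Marco (-4.53 ± 0.71), Rims4 (-3.88 ± 0.77), Ifi27l2b (-3.69 ± 0.69), Nipal2 (-3.61 ± 0.60), Lrp2 (-3.25 ± 0.59), Mmd2 (-2.31 ± 0.40) and the mitochondrial folate enzyme Mthfd2 (-2.24 ± 0.44). A2ml1 stood at 14.6 ± 4.52 CPM in controls, 39.7 ± 21.3 in E2f78DKO, 23.0 ± 22.6 in PtenKO and 1.32 ± 0.345 in TKO. Asns stood at 1.86 ± 1.68, 3.25 ± 1.82, 6.86 ± 5.42 and 0.470 ± 0.203 in the same order. Positive terms were those of Cyp2c54 (3.83 ± 0.76), Cyp2c50 (3.53 ± 0.57), the long non-coding Dleu2 (1.65 ± 0.32), the kinase genes Map2k6 (1.63 ± 0.32) and Dyrk2 (1.26 ± 0.21), Mcc (1.63 ± 0.28), the ubiquitin ligase Rnf152 (1.58 ± 0.30), Arhgef40 (1.20 ± 0.23), the Wnt receptor Fzd4 (1.19 ± 0.23) and the polymeric immunoglobulin receptor Pigr (1.17 ± 0.24). The term of the clock gene Per3 was 1.11 ± 0.23. These genes had adjusted p up to 0.0492. Of 17 Kupffer cell and macrophage markers, Marco among them, 0 had a positive term, 1 was called and 12 were negative adjusted over the list alone (median log2 -1.10, fry adjusted p = 0.0605). Of 12 acute-phase and cytokine genes 0 were called and 9 were negative adjusted over the list alone (median log2 -4.95, fry adjusted p = 0.160), and of 4 neutrophil markers 0 and 3 (median log2 -4.84, fry adjusted p = 0.134). E2f78DKO 3 and PtenKO 3 both enter this term with a minus sign, and without them the 3 medians were -0.71, -1.16 and -1.43 (fry adjusted p = 0.148, 0.170 and 0.0332, the last 0.285 with an estimated correlation). Of 13 ER stress and ATF4 targets 1 had a negative term, Asns, and 5 adjusted over the list alone (median log2 -0.92, fry adjusted p = 0.00350, 0.00774 with the library set, and 0.0834 with an estimated correlation). Of 15 circadian clock genes 1 had a positive term, Per3, and 2 adjusted over the list alone (median log2 0.43, fry adjusted p = 0.0375, 0.0379 with the library set, and 0.386 with an estimated correlation). The circadian call held in 8 of the 16 fits that left out a library, and was lost without control 1, 2 or 3, E2f78DKO 2, PtenKO 1 or 3, or TKO 3 or 4, with an adjusted p of up to 0.0919 (without control 3).

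In all, 51 genes passed, 21 with a positive and 30 with a negative term, and 12 passed with the library set in the model, 8 positive and 4 negative. Among the named genes Mcc, Rnf152, Dyrk2 and A2ml1 passed there. With the code letter as a covariate edgeR called 0, with 1366 at an unadjusted p under 0.05. Without E2f78DKO 3 and PtenKO 3 the count was 79, and 84 with the set as well. None of the 21 named genes with a call kept it in all 16 fits that left out a library, with A2ml1 called in 13, and the count ran from 1 without TKO 1 to 184 without control 3. It was 12, 10 and 5 without control 1, 2 and 4, 142, 15 and 4 without E2f78DKO 1, 2 and 4, 23, 8 and 4 without PtenKO 2, 3 and 4, and 2, 9 and 4 without TKO 2, 3 and 4.

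Each labelled deletion was also compared across the 2 backgrounds, over 14844 genes, in pairs of comparisons that share no library. With the set in the model this no longer holds, as 1 set term fitted over all libraries enters both differences of a pair. These correlations are across genes, which are not independent replicates. Log2 differences of E2f78DKO against control and of TKO against PtenKO had Pearson's r = 0.0245 and Spearman's rho = 0.0516, and r was -0.199 with the library set. With each library left out this r ran from -0.154 (without control 3) to 0.227 (without PtenKO 3). Those of PtenKO against control and of TKO against E2f78DKO had r = 0.205 and rho = 0.142, and r was 0.141 with the set. There r was 0.0974 at a mean of 5 CPM or more, and ran from 0.119 without TKO 4 to 0.364 without PtenKO 3. Of the 858 genes called between PtenKO and control, 611 (71.2%) had the same sign between TKO and E2f78DKO, with a median of 0.23 in that direction against 1.15 where they were called. Of the 421 genes called between TKO and E2f78DKO, 311 (73.9%) had the same sign between PtenKO and control, with a median of 0.27 against 1.03. No table here separates a smaller difference in the other comparison from the effect of choosing genes by their call. Both called the same 77 genes higher, such as Pls1 and Pparg, where independent lists would share 5.80, and the same 18 lower, such as Slc39a4 and Kyat3, where they would share 6.37. With the set these were 18 higher against 0.379 and 4 lower against 0.218. The numbers for independent lists take every gene as equally likely to be called. Both lists came from 1 fit with the same spread per gene, so larger shares are no test of a common effect.

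**Figure D5:**
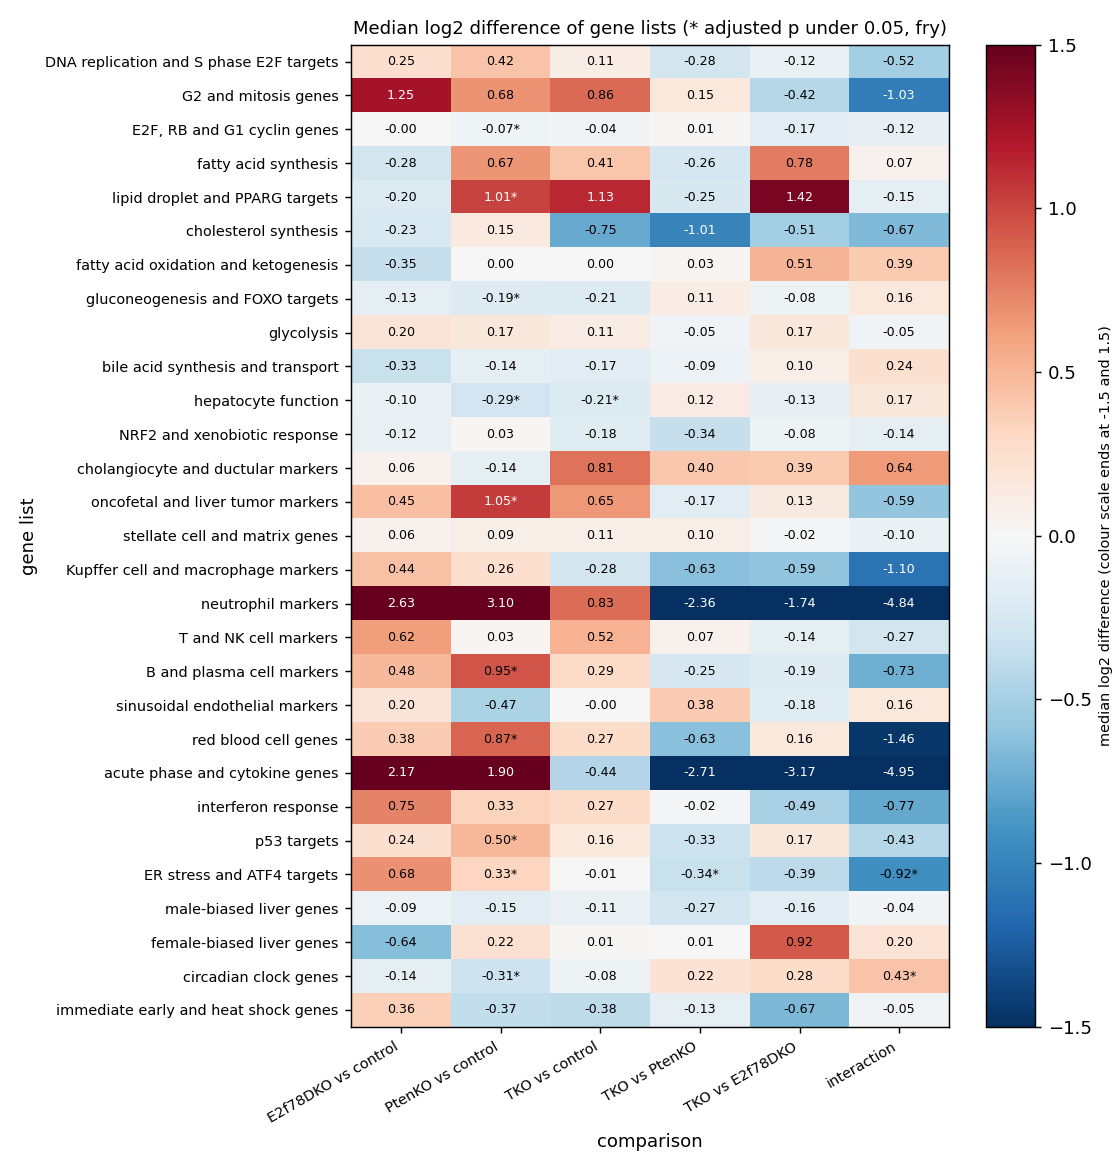
Median log2 difference of each of 29 gene lists (vertical axis) in the 5 comparisons and the interaction (horizontal axis), with an asterisk where fry passed an adjusted p of 0.05 and colours that end at a log2 of -1.5 and 1.5. The 14 asterisks include 10 for PtenKO against control, and the hepatocyte function list has one there (-0.29) and one for TKO against control (-0.21).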

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

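The tests of reads shared with pseudogenes, of mislabelled libraries, of Gm2788 reads and of the mitochondrial share, and the spread required of the position test, were chosen only after the result was seen. Library sets were read from the data, and Lars2, Lcn2, Saa1 and Gm2788 were chosen after their values were seen.

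Within each group of 4, the gap of the highest or lowest library to its neighbour was divided by the range of the group. Of 636 such tests, 61 passed Dixon's critical value, where chance gives about 1 in 20, or 31.8. Many of the genes tested were named because they differed between groups, so these tests are not independent. The ratio is given for each.

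PtenKO 3 stood apart in 15 tests and E2f78DKO 3 in 11. For PtenKO 3 the ratios were 0.927 for A2ml1, 0.843 for Adgrv1, 0.885 for Asns, 0.832 for Btg2, 0.932 for Cyp2e1, 0.932 for Ddit4, 0.996 for Lcn2, 0.885 for Marco, 0.846 for Rims4, 0.985 for Saa1, 0.899 for Slc4a1 and 0.981 for Trat1. Its list means stood apart at 0.968 for stellate cell and matrix genes, 0.894 for neutrophil markers and 0.917 for acute phase and cytokine genes. For E2f78DKO 3 they were 0.866 for Gm2788, 0.947 for Lcn2, 0.868 for Pten, 0.883 for Rps10, 0.907 for Saa1, 0.933 for Scand1, 0.849 for Scara5, 0.916 for Tpt1, 0.913 for Trat1, 0.885 for Vnn1 and 0.937 for Zfp771.

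Control 3 and TKO 4, of the smaller set, stood apart in 5 tests each. For control 3 the ratios were 1 for C1s2, 0.984 for Lars2, 0.899 for Lcn2, 0.847 for Rab43 and 0.962 for the mean of G2 and mitosis genes. For TKO 4 they were 0.838 for Cux2, 0.873 for Hbb-bt, 0.967 for Lars2, 0.852 for Lcn2 and 0.892 for the mean of oncofetal and liver tumor markers.

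E2f78DKO 1 stood apart for Atf3 (0.894), Cyp2c37 (0.838), Cyp2c54 (0.853), Fzd4 (0.876), Slc4a1 (0.865), the mean of Kupffer cell and macrophage markers (0.862), and C1s2 and Cidea (1 each, at 0.0357 CPM against 0 in its group). Control 1 did for Cux2 (0.846), Dyrk2 (0.894), Oat-rs1 (0.870) and the means of fatty acid synthesis (0.852) and male-biased liver genes (0.858), control 2 for Eda2r (0.831) and control 4 for Vnn1 (0.861). PtenKO 1 did for Adgrf1 (0.886), Pik3c2g (0.863) and Rrm2 (0.909), PtenKO 2 for Tpt1 (0.873) and PtenKO 4 for Dnase1l3 (0.842). TKO 1 did for Ifi27l2b (0.933), TKO 2 for Atf3 (0.870), Hk2 (0.871) and the mean of acute phase genes (0.858), and E2f78DKO 2 for the mean of B and plasma cell markers (0.845).

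The interaction term passed its test for 51 genes, against 0 with the code letter as a covariate and 1 with TKO 1 left out. Among named genes the log2 terms were 3.83 for Cyp2c54, 3.53 for Cyp2c50, 1.65 for Dleu2, 1.63 for Map2k6, 1.63 for Mcc, 1.58 for Rnf152, 1.26 for Dyrk2, 1.20 for Arhgef40, 1.19 for Fzd4 and 1.17 for Pigr. Negative terms were -5.54 for A2ml1, -4.81 for Scara5, -4.68 for Asns, -4.53 for Marco, -3.88 for Rims4, -3.69 for Ifi27l2b, -3.61 for Nipal2, -3.25 for Lrp2, -2.31 for Mmd2 and -2.24 for Mthfd2. The ER stress and ATF4 list passed with a negative term (fry adjusted p = 0.00350, and 0.0834 with camera's estimated correlation) and the circadian list with a positive one (fry adjusted p = 0.0375, and 0.386), the latter in 8 of the 16 fits that left out a library, with up to 0.0919 without control 3. Of 100 groupings of the 16 libraries, the real one included, 2 called at least as many genes. Drawn groups mix libraries of groups that differ, which widens their spread, so this count neither excludes chance nor bears on the interaction. The highest other grouping called 176 against the real 51, which points to a structure of the samples. It put all 6 libraries of the smaller set on the same side of the term and 1 acute-phase library on each side, and with the set in the model the real grouping called 12. The next highest other grouping called 40, and 95 called none.

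For pairs of groups, fits of the 2 groups alone were repeated over all 35 splits of their 8 libraries. In each pair 1 split, the real one, called as many genes. That is the lowest share 35 splits can give, and it was not adjusted over the pairs. It argues against a chance split of the 8 libraries in each pair but does not exclude it. The real split called 1 gene, Gm2788, against a highest other of 0 for E2f78DKO and control, which says nothing on other genes, 811 against 0 for PtenKO and control, and 333 against 2 for TKO and control. It called 1825 against 0 for TKO and PtenKO and 239 against 4 for TKO and E2f78DKO. In PtenKO and control, as in TKO and PtenKO, 5 of the 8 libraries were of the smaller set, so these splits do not exclude an effect of the set.

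The first pattern was the loss of calls against PtenKO once the library set entered the fit, from 858 to 64 for control and from 1248 to 16 for TKO. Reads shared with pseudogenes stay open: in protein-coding genes alone 11.7 and 102.7 genes were called without the set per gene called with it, but a gene that shares reads with a pseudogene can itself be protein-coding. A set difference as the whole cause was read from the position of the odd library between its own group (0) and PtenKO (1), over genes called without it: 0.674 for control 3 (quartiles 0.290 to 0.936) and 0.464 for TKO 4 (0.150 to 0.794), where the other libraries lay at -0.0676 to 0.0942. TKO 4 lay below the bound of 0.5 and control 3 above it, neither by more than its spread. Set and genotype therefore cannot be told apart for many of these genes, since 1 library a comparison separates them and standard errors grew with the set term. Simulated set differences of the fitted size, with no group difference, gave 0 calls in both comparisons. With no group difference in those data the adjusted threshold is harder to reach than in the real fits. The 0 calls therefore do not exclude set effects among the real calls. A processing difference between sets and an effect of Pten loss may both contribute, and the loss of Pten stays open as a biological explanation.

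The second pattern was higher E2f8 and lower Gm2788 counts in the libraries labelled E2f78DKO or TKO. Of those 8, 0 lay inside the Gm2788 range of the other 8, which is the pattern itself and leaves mislabelled libraries open, since an exchange of whole groups would give the same. With the labels went Pten, at most 109 CPM in PtenKO and TKO libraries and at least 121 in the others (though with the set its call between PtenKO and control was lost, adjusted p = 0.118), and E2f7 between TKO and PtenKO (-2.42, adjusted p = 0.0195, and 0.232 with the set) but not between E2f78DKO and control (0.13). The direction of the pattern goes against reads of Gm2788 counted for E2f8 as its cause, as they would have lowered E2f8 where Gm2788 fell, while its log2 difference between TKO and PtenKO was 3.10 ± 0.64. A candidate explanation left open is transcription through a deleted E2f8 locus with remaining exons counted, which gene-level counts cannot test.

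The third pattern was high acute-phase genes in E2f78DKO 3 and PtenKO 3, with E2f78DKO 2 and 4 lower but also above all 4 controls for Saa1 and Lcn2. All 4 PtenKO libraries were above the controls for Lcn2 as well, at 10.1 CPM or more against up to 9.47. For Saa1 the PtenKO libraries other than PtenKO 3 ran from 99.5 to 412 CPM, where controls reached 185. Cells of another type, neutrophils, were read from 4 of 12 markers that were measured. In 2 of the 2 libraries their mean log2 CPM (2.04 and 2.97) lay above the highest of the other 14 (0.138). Neutrophils may thus be part of the pattern, though Saa1 is made by hepatocytes, which can also make Lcn2. RNA quality was read from the mitochondrial share and stays open. The share of E2f78DKO 3 lay above the highest of the others (3.78%), and that of PtenKO 3, 1.66%, lay below their lowest (1.91%). Only 1 library was thus beyond them on the same side, so the share did not shift the same way in both. The test cannot decide on RNA quality, since both libraries lay outside the range of the others and it was chosen after these values were seen. An inflamed liver in these mice was not tested apart from this, as the labels give no such group.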

How the results depend on the processing

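The library set, the larger set only, leaving out E2f78DKO 3 and PtenKO 3, and protein-coding genes only were alternatives chosen after seeing the data. Counts are given for E2f78DKO, PtenKO and TKO against control, TKO against PtenKO, TKO against E2f78DKO and the interaction, in this order, where the reported counts were 2, 858, 145, 1248, 421 and 51. Unless stated, the cause was not tested.

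DESeq2 called 22, 1579, 415, 2033, 990 and 590 genes, and limma-voom with quality weights 38, 3266, 408, 3414, 1366 and 1269. With RLE factors all 6 counts were within 1.5 times those reported. Only the groups compared gave 1 for E2f78DKO against control, 333 for TKO against control and 239 for TKO against E2f78DKO, and does not apply to the interaction. A mean of at least 5 CPM, with fewer genes tested, gave 447 for PtenKO and 96 for TKO against control, and no filter 751 for TKO against PtenKO. Against a minimum fold of 1.5 the counts were 1, 128, 39, 20, 40 and 0, a stricter question by construction. The code letter as a covariate gave 1, 47, 0, 28, 0 and 0.

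Replicate numbers did not pair the samples in all groups: 6 of 24 same-number pairs had r over 0.1 (-0.236 to 0.338), and 7 of 16 libraries matched best to their own number. Same-number pairs among control, E2f78DKO and PtenKO all had a positive r (0.0228 to 0.338), so a pairing of these groups stays open. Those with TKO were negative but for E2f78DKO 4 and TKO 4 (0.148). With the replicate block the count was 1 for E2f78DKO against control and 78 for the interaction. A sex covariate does not apply, as all 16 libraries had the male pattern.

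The library set as a covariate gave 1 for E2f78DKO against control, 64 for PtenKO against control, 16 for TKO against PtenKO, 281 for TKO against E2f78DKO and 12 for the interaction. The larger set only gave 1 for E2f78DKO and 69 for TKO against control and 160 for TKO against E2f78DKO, with 3 or 4 libraries a group, and cannot be run where PtenKO is compared. Without the acute-phase libraries the counts were 5, 1495, 445, 1949, 690 and 79, and with the set as well 5, 230, 601, 74, 701 and 84. Protein-coding genes only gave 0 for E2f78DKO against control, and with the set 0, 63, 10, 277 and 13 for all but TKO against control.

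Leaving out each library gave 1 to 3, 301 to 1740, 65 to 285, 303 to 2409, 169 to 746 and 1 to 184 genes. E2f78DKO against control called 3 without PtenKO 3, and 1 without any one control, E2f78DKO 2, 3 or 4, PtenKO 1 or 2, or TKO 1, 3 or 4. The other libraries that moved a count over 1.5 times are named with each comparison in the report.

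The correlation across genes of the first pair, 0.0245, was -0.0545 at 5 CPM or more and -0.199 with the set, and ran from -0.154 without control 3 to 0.227 without PtenKO 3. It was -0.0231 without E2f78DKO 1, -0.0214, -0.00122 and -0.0142 without PtenKO 1, 2 and 4, and -0.00209 and -0.0164 without TKO 2 and 3. That of the second pair, 0.205, was 0.0974 at 5 CPM or more and 0.141 with the set, and ran from 0.119 without TKO 4 to 0.364 without PtenKO 3.

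Signs turned for genes with no call, and for Clec2h. Pten in E2f78DKO against control (0.16) was -0.0445 with limma-voom, -0.0104 with the code letter, -0.0153 without the acute-phase libraries and -0.11 with the set as well, and ran from -0.0140 without E2f78DKO 3 to 0.23. E2f7 there (0.13) was -0.11 with limma-voom, -0.0623 in the larger set only, -0.28 without the acute-phase libraries, -0.40 with the set as well, and ran from -0.28 without E2f78DKO 3 to 0.63, with -0.22 and -0.0622 without control 1 and 3. E2f8 in PtenKO against control (0.0626) was -0.0628 with the replicate block and -0.0613 without the acute-phase libraries, and ran from -0.18 without control 3 to 0.61, with -0.0848 and -0.0590 without control 4 and PtenKO 3. E2f7 in TKO against control (-0.48) ran from -1.06 to 0.0262 without control 4. Clec2h in TKO against E2f78DKO (-2.86) was 1.02 with the code letter (adjusted p = 1). In the interaction Pten (0.22) was -0.0102 with the set and -0.00964 in protein-coding genes with it. E2f8 there (0.27) was -0.31 with the set, -0.30 in protein-coding genes with it, and ran from -0.28 without control 2 to 0.91, with -0.00246 without TKO 3. Gm2788 there (-0.52) was 0.29 with the code letter and 0.0930 without the acute-phase libraries and with the set.

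Of 198 named results with a call, 198 kept it with RLE factors, 196 of 197 with DESeq2, 194 with limma-voom, 186 with the replicate block, 146 with no filter, 137 of 173 with only the groups compared, 142 of 145 at 5 CPM or more, 189 of 190 in protein-coding genes only and 182 of 197 without the acute-phase libraries. With the set 78 kept it, with the code letter 18, against a minimum fold of 1.5 62, and 89 in every fit with a library left out. Of 14 list calls 5 held with the set, 6 with the replicate block, 3 with the code letter, 11 without the acute-phase libraries, 11 with camera's preset correlation, 0 with its estimated one, and 3 in every fit with a library left out. Lists without a call gained 1 with the set and 13 without the acute-phase libraries. Depth limits genes at low counts, and in simulated data a 1.5-fold change was recovered for 7.46% of genes in E2f78DKO against control.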

Other observations

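Other gene lists were tested in every comparison, and none of those below passed fry in any of them with all libraries. The sinusoidal endothelial and the female-biased lists did so in PtenKO against control once E2f78DKO 3 and PtenKO 3 were left out. Of 22 fatty acid oxidation and ketogenesis genes Vnn1, a pantetheinase, rose in PtenKO against control (3.16 ± 0.67, adjusted p = 0.0148), with 2 higher adjusted over the list alone (fry adjusted p = 0.998). In TKO against E2f78DKO their median log2 was 0.51 with 0 called and 1 higher adjusted over the list alone (fry adjusted p = 0.206). Of 15 glycolysis genes Hk2, a hexokinase, rose in PtenKO against control (1.31 ± 0.30) and fell in TKO against PtenKO (-1.18 ± 0.30), by either count in each (fry adjusted p = 0.181 and 0.641). Of 14 bile acid synthesis and transport genes the exporter Abcc2 fell in PtenKO against control (-0.58 ± 0.16), 1 of 14 by either count (fry adjusted p = 0.179). Of 18 NRF2 and xenobiotic response genes Gstm3, a glutathione transferase, fell in TKO against PtenKO (-1.72 ± 0.49), with 0 adjusted over the list alone (fry adjusted p = 0.641). That list had a positive median in PtenKO against control (0.03) and a negative direction in fry.

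Of 10 cholangiocyte and ductular markers Epcam rose in TKO against PtenKO (1.52 ± 0.39), 1 by either count (fry adjusted p = 0.426). Their median in PtenKO against control was -0.14, with a mean of 0.16 and a positive direction in fry. Of 22 stellate cell and matrix genes Tgfb1 fell in PtenKO against control (-1.46 ± 0.25), as did Reln, 2 by either count (fry adjusted p = 0.882), and Tgfb1 rose in TKO against PtenKO (1.40 ± 0.26, fry adjusted p = 0.641). That list had a positive median in PtenKO against control (0.09) and a negative direction in fry. Of 12 sinusoidal endothelial markers Dnase1l3 fell in PtenKO against control (-0.86 ± 0.20), with 4 lower adjusted over the list alone (fry adjusted p = 0.138). In that fit without 2 libraries 4 fell and 10 did so adjusted over the list alone, and the list passed (median log2 -0.59, fry adjusted p = 0.0383, and 0.372 with an estimated correlation). Of 10 female-biased liver genes 0 were called by either count in PtenKO against control (median log2 0.22, fry adjusted p = 0.469). Without the same 2 libraries 0 were called and 3 were higher adjusted over the list alone, and that list passed (median log2 0.44, fry adjusted p = 0.0382, and 0.325 with an estimated correlation). PtenKO 3 lay against both of these list calls. Its mean log2 CPM was the highest of its group for endothelial markers (4.64, others 3.31 to 4.32). For female-biased genes it was the lowest (2.51, others 3.56 to 4.36). Of 16 male-biased liver genes Susd4 fell in PtenKO against control, with 2 higher and 2 lower adjusted over the list alone (fry adjusted p = 0.614). It also fell in TKO against control (-1.79 ± 0.32), with 3 lower adjusted over the list alone (fry adjusted p = 0.391), and Mup20 fell in TKO against PtenKO (-1.79 ± 0.52), with 0 adjusted over the list alone. In TKO against E2f78DKO the transporter Slco1a1 rose (0.98 ± 0.20) and Serpina1e fell (-0.87 ± 0.21), with 2 higher and 4 lower adjusted over the list alone (fry adjusted p = 0.727). Of 11 immediate early and heat shock genes Ier2 (-1.42 ± 0.31) and the chaperone Hspa8 (-1.23 ± 0.28) fell in PtenKO against control, with 1 higher and 4 lower adjusted over the list alone (fry adjusted p = 0.181). In TKO against PtenKO Ier2 (1.91 ± 0.32) and Junb (1.94 ± 0.48) rose, 2 by either count (fry adjusted p = 0.520), where the median of the list was -0.13, its mean 0.23 and the direction of the test positive.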
